A study of Mus musculus with 88 samples.

How the data were processed

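The series holds 88 RNA sequencing libraries from 44 C57BL/6 mice, 1 library per hemisphere and animal. Per the labels, cortical impact was given through a 3 mm craniotomy over the right somatosensory cortex with a 2 mm tip at 6.0 m/s, 1 mm depth and 100 ms dwell, with buprenorphine at 0.05 mg/kg. The mice were perfused, and 4 mm punches were taken from the injured and the opposite cortex at 24 or 72 h or from naive mice, whose right punch is labelled ipsilateral. Polyadenylated RNA was sequenced to at least 20 M reads per library, per the labels' protocols. Reads were aligned with HISAT2 2.0.5 to mm10, per the submitters' processing notes; the counting program, the annotation release and the strand of the libraries are not given in the sources used here. The authors deposited 1 table of raw counts per gene and library, and all values below start from these deposited counts. Plasma levels of testosterone, androstenedione, dehydroepiandrosterone, progesterone and estradiol stand in the labels as log10 values, per the labels in ng/ml except estradiol in pg/ml, and how the authors treated values below the limit of detection is not given. The CPM and log2 values were computed here from the deposited counts.

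The table has 54532 genes, of which 54409 were matched to symbols and positions in GENCODE M21 (GRCm38), a reference that may differ from the authors' own. The 123 genes without a symbol held 0.062% of counts, and 101 symbols are shared by several identifiers. Libraries were assigned by the sex, treatment, side and animal named in the labels. The ipsilateral library of animal PM1 has labels that contradict each other on sex, was left unassigned, and enters no comparison, so 87 libraries were compared. The batch letters A, B and C come from the labels: batch A holds naive and 24 h animals, batch B all times, and batch C 72 h animals alone. Total counts were 10.6 to 26.36 M per library (median 16.25), and mitochondrial genes held 2.35 to 10.48% of counts. The median standard error of a log2 fold change was 0.1759 in females and 0.1752 in males at 24 h, and 0.2201 and 0.2346 at 72 h. In a search for duplicated libraries the closest pair of a group differed with a chi-square of 2.74 per gene, so no library of a group duplicates another of that group; pairs across groups were not compared.

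Ipsilateral libraries (43, 19126 genes tested, 35 residual degrees of freedom, common biological coefficient of variation 0.2344) and contralateral libraries (44, 18436 genes, 36, 0.2128) were each fitted with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): filterByExpr on the groups, TMM normalization, a batch term and the quasi-likelihood F test, two-sided. Side comparisons used 86 libraries of 43 animals (19946 genes, 37, 0.1624) with the animal as a block; this pairing comes from the animal named in the labels. P values were adjusted by Benjamini-Hochberg over all genes tested, and genes were called at an adjusted p under 0.05. The comparisons were injury against naive per sex, time and side, 72 h against 24 h per sex ipsilaterally, females against males per time, the interactions of sex and injury, the 2 sides per sex and time, the interactions of sex and side, and the slope of expression on each hormone level within groups (testosterone in males alone). The standard error was taken from the log2 fold change and the F statistic. A gene without counts in the lower group is given as at least the fold that 3 counts over that group would allow.

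Gene lists for 35 cell types and processes were fixed before the data were examined, as were the comparisons, the tests, the other settings tried and the rule for the genes named. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists of a comparison, and again with the correlation estimated from the data; fry, a rotation test, was run beside it. Members of a list were also adjusted over the list alone. Hormone levels were compared by exact permutation of the mean log10 level, or 100000 resamples where too many arrangements exist, two-sided, adjusted over 30 tests. The named genes are the 8 that rose and the 8 that fell by the largest amounts among called genes with an average log2 CPM of at least 1, up to 3 members of each list with the smallest p, all called genes where 20 or fewer were called, Gfap, Cldn5, Ocln, Tjp1, Esr1, Esr2, Pgr and Xist everywhere, autosomal genes that differ by sex, and genes called for a hormone slope. A gene so named in 1 comparison is in places also given for the other sex, time or side, which was chosen after its values were seen. Some genes that meet this rule are not reported here.

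The fits were tested on simulated counts with 200 changed genes at 1.5-, 2- and 4-fold. For females at 24 h against naive they recovered 46.27, 70.15 and 90.91% of the changed genes among 19126, with 2.128% false among the calls; at 72 h they recovered 23.88, 56.72 and 87.88%. Simulated hormone differences gave p under 0.05 in 5.0% of cases without a shift and in 90.5% with a shift of 2 SD. The other settings, chosen before the data were examined, were RLE size factors, no low-count filter, DESeq2 1.42.0, no batch term, batch A or batch B alone, the first letter of the animal code as block, no replicate block, leaving out each ipsilateral library in turn, other scales of the hormone levels and the estimated correlation. Leaving out the libraries labelled PF1 ipsi and LF3, and removing a trend with gene length from each library (spline with 5 degrees of freedom), were added after the data were seen. For each comparison 30 other splits of the same libraries were also fitted. Tables and plots used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.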

Results

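Controlled cortical impact drives a piston into the exposed brain and is a standard model of contusion. Here it was delivered through a 3 mm craniotomy over the right somatosensory cortex of C57BL/6 mice of both sexes, and cortex was collected with a 4 mm punch 24 or 72 h later. RNA counts per gene were given for the injured (ipsilateral) punch and for the matching punch of the other hemisphere, and naive mice gave the same pair of punches. The labels give craniotomy, impact and buprenorphine for the injured mice alone, and no group had surgery without impact. Effects of impact and of surgery or buprenorphine therefore cannot be told apart. The labels also gave 5 plasma steroid hormone levels per animal. The design addresses whether the cortical response differs between females and males, and whether transcripts follow circulating hormones. The groups held 7 naive females, 6 naive males, 7 females and 8 males at 24 h, and 9 females and 7 males at 72 h, with a contralateral library from each. All had an ipsilateral library in the comparisons except 1 male at 72 h, which left 6. The ipsilateral library labelled PF1, of a female at 72 h, has male transcripts and was kept as labelled. Below, ± after a log2 fold change is its standard error from the model, and ± after a CPM value (counts scaled to the library size) or a hormone level is the SD between animals. Values beside a gene are log2 fold changes unless CPM is named, and a pair of values is females then males.

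The 24 h comparison asked which cortical transcripts had changed 1 day after impact, against naive cortex of the same sex. The injured cortex held far higher levels of transcripts of inflammatory signals, infiltrating leukocytes and reactive astrocytes. Il1rn, which encodes the antagonist of the interleukin-1 receptor, was at 18.7 ± 17.6 CPM in 7 injured females and had no counts in naive females, at least 692-fold higher (floor of 3 counts over the naive group). Acod1, the itaconate-producing enzyme of activated macrophages, was at least 424-fold higher in females, and Hcar2, a hydroxycarboxylic acid receptor, at least 346-fold higher in males. Sprr1a (chromosome 3, 92483952 to 92485895), a protein of injured and regrowing axons, was at least 240-fold higher in females and 130-fold higher in males. The C-type lectin receptors Clec4d and Clec4e, the coagulation factor F10 and the inflammasome gene Mefv also had no counts in the naive group they were compared with, and were at least 228-fold (Clec4d, females), 281-fold (Clec4e, males), 150- and 196-fold (F10, females and males) and 132-fold higher (Mefv, males). Slfn4, a myeloid gene, was at 59.4 ± 68.7 CPM in females and 72.3 ± 35.8 CPM in 8 males at 24 h.

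All 16 measured cytokine and chemokine transcripts rose in both sexes at 24 h. Ccl2, which recruits monocytes (chromosome 11, 82035571 to 82037453), rose by 7.49 ± 0.46 and 7.81 ± 0.52 log2 units in females and males. Cxcl10, an interferon-induced chemokine, rose by 7.45 ± 0.52 and 7.00 ± 0.52, and the cytokine Lif by 5.05 ± 0.39 and 5.31 ± 0.41. Cxcl2, a neutrophil attractant, was at 9.72 ± 15.7 and 10.7 ± 7.88 CPM; RF1 held 44.8 CPM against 1.65 to 9.17 in the other 6 females. Of 9 measured neutrophil genes 7 rose in females and 9 in males, among them the calprotectin subunit S100a9 (7.07 ± 1.00 and 5.59 ± 0.82) and the receptor Csf3r (1.94 ± 0.28 and 2.29 ± 0.28). Of 12 monocyte and macrophage genes 9 rose in each sex, including the chemokine receptor Ccr2 (4.88 ± 0.49 and 4.39 ± 0.46) and the arginase Arg1 (6.70 ± 0.74 and 7.74 ± 0.81). All 15 interferon response genes rose. Rsad2, an antiviral enzyme, was at 3.56 ± 0.46 and 3.87 ± 0.49. Of 13 complement genes 9 and 9 rose, including C4b (3.48 ± 0.24 and 3.46 ± 0.26) and the anaphylatoxin receptors C3ar1 (3.37 and 3.37) and C5ar1 (4.37 and 4.36). Of 12 antigen presentation genes 10 and 9 rose, including the immunoproteasome subunit Psmb8 (1.68 ± 0.21 and 1.88 ± 0.22). Of 12 inflammasome and necroptosis genes 9 and 9 rose and 1 and 1 fell. Zbp1, a sensor of nucleic acids, was at 4.57 ± 0.44 and 3.44 ± 0.41. Of 3 measured lymphocyte genes 1 and 1 rose, the T-cell coreceptor Cd4 (1.18 ± 0.37 and 1.23 ± 0.36), which microglia and macrophages can also carry. By the competitive list test (camera, Benjamini-Hochberg adjusted over 35 lists, two-sided), the cytokine, complement and interferon lists were higher in females (adjusted p = 2.2e-25, 5.29e-08 and 8.79e-12) and males (4.81e-26, 8.35e-08 and 4.26e-13). With an estimated correlation the interferon list had adjusted p = 0.0558 in females. The neutrophil list had adjusted p = 1.11e-05 and 1.28e-05, and 0.122 and 0.124 with an estimated correlation. The monocyte list had adjusted p = 5.29e-08 and 2.22e-09, and 0.0636 and 0.0344 with an estimated correlation. The antigen presentation list had adjusted p = 1.33e-06 and 9.66e-07 (0.0695 and 0.0636 with an estimated correlation), the inflammasome list 7.4e-05 and 2.99e-05 (0.16 and 0.133 with an estimated correlation) and the lymphocyte list 0.563 and 0.147. In females, adjusted over the list alone, 8 rose of the neutrophil genes, 10 rose of the complement genes, 11 rose of the antigen presentation genes and 10 rose of the inflammasome genes. So adjusted, in males 10 rose and 1 fell of the complement genes, 10 rose of the antigen presentation genes and 3 rose of the lymphocyte genes. All other counts above stayed. Moved by over 1.5 times with 1 library fewer (log2): in males Ccl2 to 9.00 without KM2, Cxcl10 to 7.61 without CM1, S100a9 to 4.33 and 7.01 without DM2 or EM3, Ccr2 to 5.26 without EM3 and Arg1 to 8.44 without EM2; in females S100a9 to 7.70 without KF2, Arg1 to 7.67 without GF3 and Rsad2 to 2.73 without DF3.

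Astrocyte transcripts split in opposite directions at 24 h. All 12 reactive astrocyte genes rose in both sexes. Gfap, the intermediate filament protein of astrocytes (chromosome 11, 102887336 to 102900912), went from 88.8 ± 17.2 to 1640 ± 374 CPM in females (log2 fold change 4.18 ± 0.21, adjusted p = 1.68e-19) and from 84.9 ± 17.9 to 1380 ± 229 CPM in males (4.00 ± 0.21, adjusted p = 3.33e-18; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, n = 7 against 7 and 8 against 6). Serpina3n, a secreted protease inhibitor, rose by 4.89 ± 0.22 and 4.56 ± 0.22 and the adhesion receptor Cd44 by 5.22 ± 0.25 and 5.19 ± 0.26. Of 12 homeostatic astrocyte genes 9 fell in females and 10 in males, including glutamine synthetase Glul (-1.14 ± 0.11 and -1.11 ± 0.10) and the gap junction genes Gja1 (-1.27 ± 0.15 and -1.23 ± 0.14) and Gjb6 (-1.22 ± 0.15 and -1.29 ± 0.15), while 1 rose in females and 0 in males. The list test gave adjusted p = 2.2e-25 and 4.47e-24 for the reactive genes. For the homeostatic genes it gave 5.07e-07 and 2.72e-07, and 0.122 and 0.113 with an estimated correlation. Markers of resting microglia also divided: P2ry12, a purinergic receptor of surveying microglia (chromosome 3, 59216272 to 59262871), fell by 2.12 ± 0.18 and 2.07 ± 0.18, and Siglech by 1.90 ± 0.28 and 1.86 ± 0.28, while Fcrls rose by 1.66 ± 0.21 and 1.46 ± 0.21. In all, 6 of 12 homeostatic microglia genes fell and 2 rose in each sex (list adjusted p = 0.0238 and 0.0505; 0.488 and 0.55 with an estimated correlation). Of 14 activated microglia genes 10 rose and 1 fell in each sex (list adjusted p = 6.21e-08 and 3.99e-08), among them the galectin Lgals3 (6.35 ± 0.53 and 8.11 ± 0.64), the matrix protein Spp1 (4.38 ± 0.42 and 4.29 ± 0.43) and the tetraspanin Cd9 (1.72 ± 0.16 and 1.66 ± 0.16). When members were adjusted over the list alone, in females 10 fell of the homeostatic astrocyte genes and 11 rose of the activated microglia genes. By the same adjustment in males 1 rose of the homeostatic astrocyte genes. The remaining counts stayed. With 1 library fewer these fold changes (log2) moved by over 1.5 times: in females Lgals3 to 7.07 without CF3; in males Lgals3 to 9.19 without EM3.

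**Figure D1:**
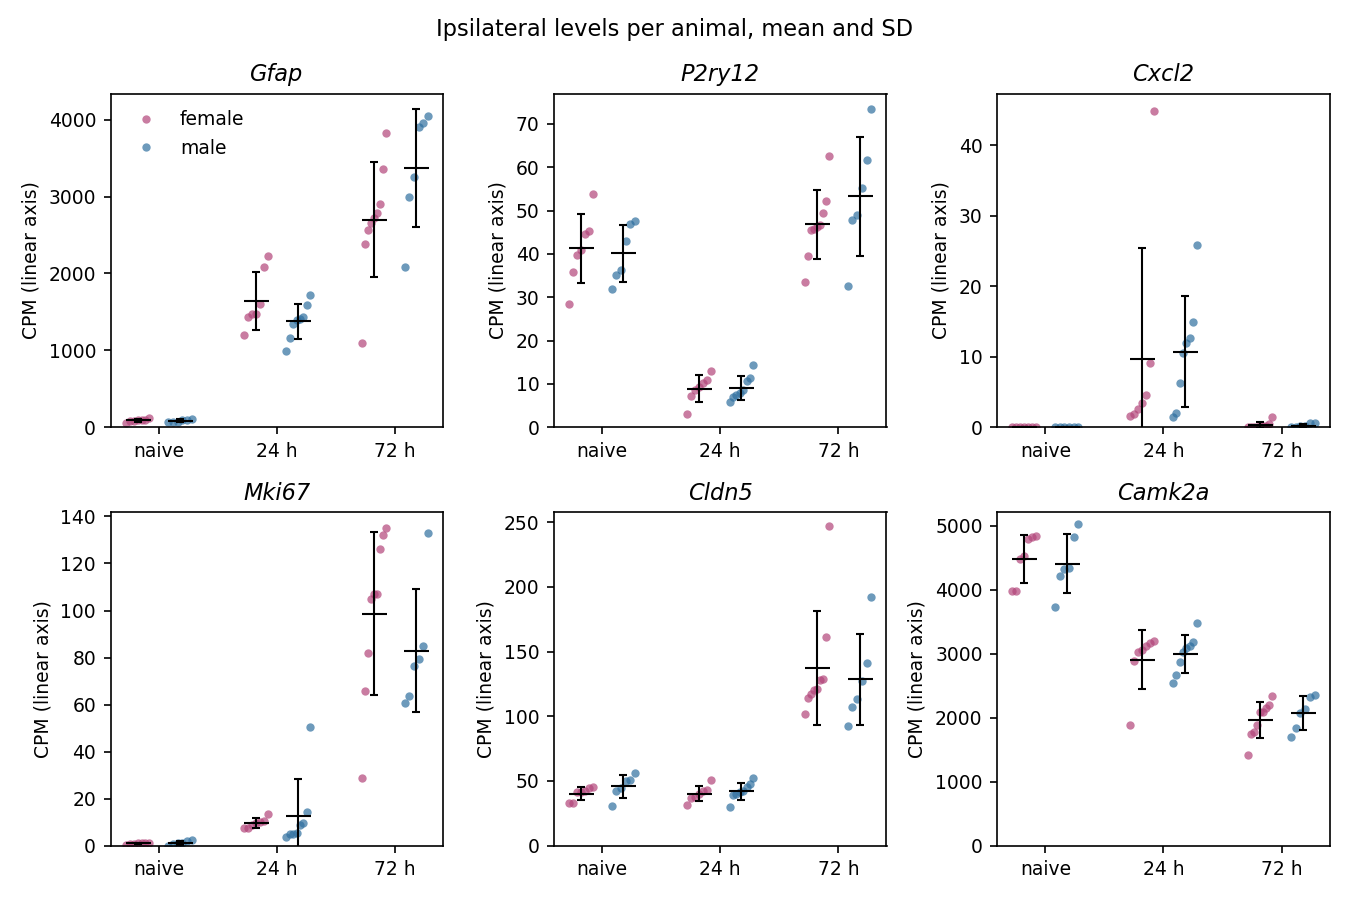
Levels in the ipsilateral punch of 6 transcripts, in CPM on linear axes, by sex and time. Points are animals and bars are mean and SD; Gfap averaged 88.8 ± 17.2 CPM in naive females and 2700 ± 747 CPM at 72 h, and P2ry12 averaged 41.3 ± 8.03, 8.84 ± 3.13 and 46.8 ± 8 CPM in naive females, at 24 h and at 72 h.

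Some neuronal transcripts were lower at 24 h. Camk2a, a kinase of excitatory synapses (chromosome 18, 60925618 to 60988152), fell by 0.63 ± 0.11 in females and 0.56 ± 0.10 in males, Lamp5, a marker of one interneuron class, had log2 fold changes of -2.03 ± 0.27 and -1.80 ± 0.26, the peptide gene Vip of -1.27 ± 0.18 and -1.10 ± 0.17, and the presynaptic syntaxin Stx1a of -1.28 ± 0.16 and -1.19 ± 0.15. Of 12 genes each, 4 and 5 excitatory neuron, 5 and 4 inhibitory neuron and 6 and 6 synaptic genes fell in females and males, and none of these members rose. Adjusted p was 0.0298 and 0.0182 for the excitatory list (0.279 and 0.229 with an estimated correlation), 0.00732 and 0.0402 for the inhibitory list (0.279 and 0.409 with an estimated correlation) and 0.00588 and 0.00256 for the synaptic list (0.279 and 0.229 with an estimated correlation). Activity-dependent immediate early genes rose in part (6 of 12 in each sex; list adjusted p = 0.136 and 0.248), led by Fosb (2.89 ± 0.66 and 2.70 ± 0.67) and the neuronal pentraxin Nptx2 (1.93 ± 0.46 and 2.20 ± 0.49); in the males of batch B alone this list's median was -0.09, against 0.91 over all males. Of 12 axon injury genes 7 and 7 rose and 0 and 1 fell (list adjusted p = 3.8e-07 and 2.12e-06), including the transcription factors Atf3 (5.89 ± 0.29 and 6.36 ± 0.32) and Jun (1.60 ± 0.11 and 1.69 ± 0.12). Transcripts that mark neighbouring hippocampus, striatum and thalamus rose for 6 and 4 of 12 and fell for 1 and 2 (list adjusted p = 0.122 and 0.338). Prkcd, abundant in thalamus, was at 0.91 ± 0.20 and 1.04 ± 0.20. Adjusted over the list alone, in females 1 rose of the excitatory neuron genes and 8 rose of the neighbouring-region genes. Likewise in males 6 fell of the excitatory neuron genes and 8 rose of the axon injury genes. Other counts given here stayed.

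At 24 h transcripts of endothelial activation were higher, while barrier genes moved in both directions. Icam1, an adhesion molecule for leukocytes, rose by 2.65 ± 0.26 and 2.43 ± 0.26, and Selp, the platelet and endothelial selectin, stood at 2.5 ± 0.95 and 2.92 ± 1.32 CPM; 9 and 10 of 14 endothelial activation genes rose (list adjusted p = 1.74e-08 and 1.57e-08). Of 15 endothelial and barrier genes 5 rose and 6 fell in each sex (list adjusted p = 0.696 and 0.533). Occludin (Ocln), a tight junction protein, fell by 0.74 ± 0.16 and 0.86 ± 0.15, and the organic anion transporter Slco1a4 by 1.48 ± 0.24 and 1.68 ± 0.24, while the endothelial cadherin Cdh5 rose by 1.17 ± 0.16 and 1.06 ± 0.16. Claudin 5 (Cldn5, chromosome 16, 18776847 to 18778262) did not pass, at -0.07 ± 0.14 and -0.17 ± 0.14 (adjusted p = 0.751 and 0.422), nor did the scaffold gene Tjp1, at 0.18 ± 0.10 and 0.13 ± 0.10 (adjusted p = 0.188 and 0.376). Of 12 pericyte and smooth muscle genes 1 rose and 3 fell in each sex (list adjusted p = 0.122 and 0.356). Vtn was at -0.76 ± 0.18 and -0.73 ± 0.18. Of 12 fibroblast and matrix genes 7 and 5 rose and 1 and 1 fell (list adjusted p = 0.0792 and 0.121). The collagen Col6a1 was at 1.05 ± 0.20 and 0.95 ± 0.20 and the growth factor Igf2 at -1.98 ± 0.45 and -2.64 ± 0.45. Genes with large falls included the matrix protein Fmod (-3.73 ± 0.48 and -3.72 ± 0.46), Myoc (-3.53 ± 0.50 and -3.38 ± 0.49), the solute carriers Slc22a8 (-3.20 ± 0.31 and -3.19 ± 0.30), Slc22a6 (-2.91 and -2.92) and Slc47a1 (-3.15 and -2.83), and the proteoglycan Ogn (-2.79 and -3.41). Red cell transcripts rose for 4 and 4 of 5 genes, with Hbb-bs at 2.63 ± 0.58 and 1.93 ± 0.58. In males Hbb-bs did not pass at 1.28 without DM2 (adjusted p = 0.0852), whose library held 261.05 CPM. The red cell list had adjusted p = 0.0233 and 0.108, and 0.346 and 0.539 with an estimated correlation. Of 9 choroid plexus and ependyma genes 2 and 1 rose (list adjusted p = 0.397 and 0.153). The water channel Aqp1 was at 3.54 ± 0.70 and 2.90 ± 0.66. In females, adjusted over the list alone, 11 rose of the endothelial activation genes. So adjusted, in males 11 rose of the endothelial activation genes and 5 rose of the red cell genes. All other counts above stayed. Leaving out 1 library moved these fold changes (log2) by over 1.5 times: in females Igf2 to -2.58 without DF2; in males Ogn to -2.31 without EM3 and Aqp1 to 5.33 without EM3.

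Lipid, stress and steroid genes formed the remaining groups at 24 h. Cholesterol biosynthesis genes rose together: 15 of 15 in females and 14 in males. Squalene epoxidase Sqle was at 0.79 ± 0.12 and 0.78 ± 0.12 and Fdft1 at 0.75 ± 0.13 and 0.81 ± 0.14. The cholesterol list had adjusted p = 6.14e-07 and 5.97e-07, and 0.134 and 0.132 with an estimated correlation. Of 12 cholesterol efflux and lipid droplet genes 3 and 4 rose and 3 and 2 fell (list adjusted p = 0.447 and 0.356). Cholesterol 25-hydroxylase Ch25h was at 5.06 ± 0.37 and 4.65 ± 0.38 and the lipid transfer protein Pltp at -1.81 ± 0.18 and -1.94 ± 0.17. Heme oxygenase Hmox1 (chromosome 8, 75093621 to 75100589) rose by 5.70 ± 0.27 and 5.52 ± 0.28; 10 and 9 of 12 oxidative stress genes rose and 1 and 1 fell (list adjusted p = 8.28e-06 and 1.43e-05). Hypoxia and glycolysis genes rose for 7 and 8 of 12 (list adjusted p = 0.0126 and 0.000403; 0.253 and 0.113 with an estimated correlation). Hexokinase Hk2 was at 1.80 ± 0.21 and 2.24 ± 0.22 and adrenomedullin Adm at 2.32 ± 0.31 and 2.63 ± 0.32. Of 12 endoplasmic reticulum stress and heat shock genes 8 and 7 rose and 1 and 1 fell (list adjusted p = 0.00279 and 0.00932; 0.117 and 0.135 with an estimated correlation). Trib3 was at 2.23 ± 0.39 and 2.16 ± 0.40. Cell cycle genes rose for 12 and 14 of 15 (list adjusted p = 2.97e-07 and 2.23e-07; 0.134 and 0.132 with an estimated correlation). Top2a was at 3.18 ± 0.42 and 3.26 ± 0.44 and the proliferation marker Mki67 at 3.54 ± 0.50 and 3.56 ± 0.50. Of 12 oligodendrocyte and myelin genes 3 and 2 rose (list adjusted p = 0.154 and 0.595). Cldn11 was at 1.08 ± 0.24 and 0.84 ± 0.24. Of 12 oligodendrocyte precursor genes 3 and 2 rose and 3 and 2 fell (list adjusted p = 0.58 and 0.237). The sialidase Neu4 was at -1.32 ± 0.17 and -1.60 ± 0.17 and the receptor Gpr17 at -0.87 ± 0.15 and -1.19 ± 0.15. Of 11 steroid synthesis and receptor genes 3 rose and 1 fell in females, and 3 rose and 2 fell in males (list adjusted p = 0.563 and 0.595): the translocator protein Tspo rose by 2.22 ± 0.40 and 1.94 ± 0.40, and the estrogen receptor gene Esr2 by 1.58 ± 0.46 and 1.42 ± 0.45, while Esr1 did not pass (0.58 ± 0.29 and 0.58 ± 0.29; adjusted p = 0.13 and 0.137). The progesterone receptor Pgr fell in males (-0.37 ± 0.11, adjusted p = 0.00737) and did not pass in females (-0.27 ± 0.11, adjusted p = 0.0614). It passed in females without any 1 of 11 libraries, SM1, SM2, LF3, QF2, RF2, SF1, SF3, TF1, TF3, RM2 or KF3 (-0.33 to -0.27, adjusted p = 0.0238 to 0.0498). Of 12 glucocorticoid response genes 4 rose and 2 fell in each sex (list adjusted p = 0.179 and 0.119). The cell cycle inhibitor Cdkn1a was at 2.07 ± 0.26 and 1.94 ± 0.27. The list of X-linked genes that escape inactivation and Y-linked genes had 1 riser of 9 in each sex, Eif2s3x (0.35 ± 0.10 and 0.29 ± 0.10; list adjusted p = 0.563 and 0.757). In males it did not pass without 1 library, any of GM2, RM1, RM2, KM2 or KM3 (0.23 to 0.29, adjusted p = 0.0522 to 0.119). When members were adjusted over the list alone, in females 5 rose and 1 fell of the myelin genes, 4 rose and 4 fell of the precursor genes, 2 fell of the steroid genes and 5 rose of the glucocorticoid genes. By the same adjustment in males 5 rose of the efflux genes, 10 rose of the oxidative stress genes, 1 rose of the myelin genes and 3 rose and 4 fell of the precursor genes. In males also 5 rose of the glucocorticoid genes and 0 rose of the X- and Y-linked genes. The remaining counts stayed. Moved by over 1.5 times with 1 library fewer (log2): in males Mki67 to 2.59 without DM2.

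Of 19126 genes tested at 24 h, 5572 passed in females (3101 rose, 2471 fell) and 5564 in males (3075 rose, 2489 fell; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). At least a doubling was seen for 1444 and 1467 genes and a fall to 50% or lower for 501 and 437. Within batch A 4693 genes passed in females and 4807 in males, and within batch B 1693 and 1445. When a trend with gene length was removed from each library, the median of all genes moved by -0.123 log2 units in females and -0.133 in males, and the share of calls that rose went from 55.7% to 37.5% and from 55.3% to 36.64%, so the split between rises and falls depends on the scaling.

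**Figure D2:**
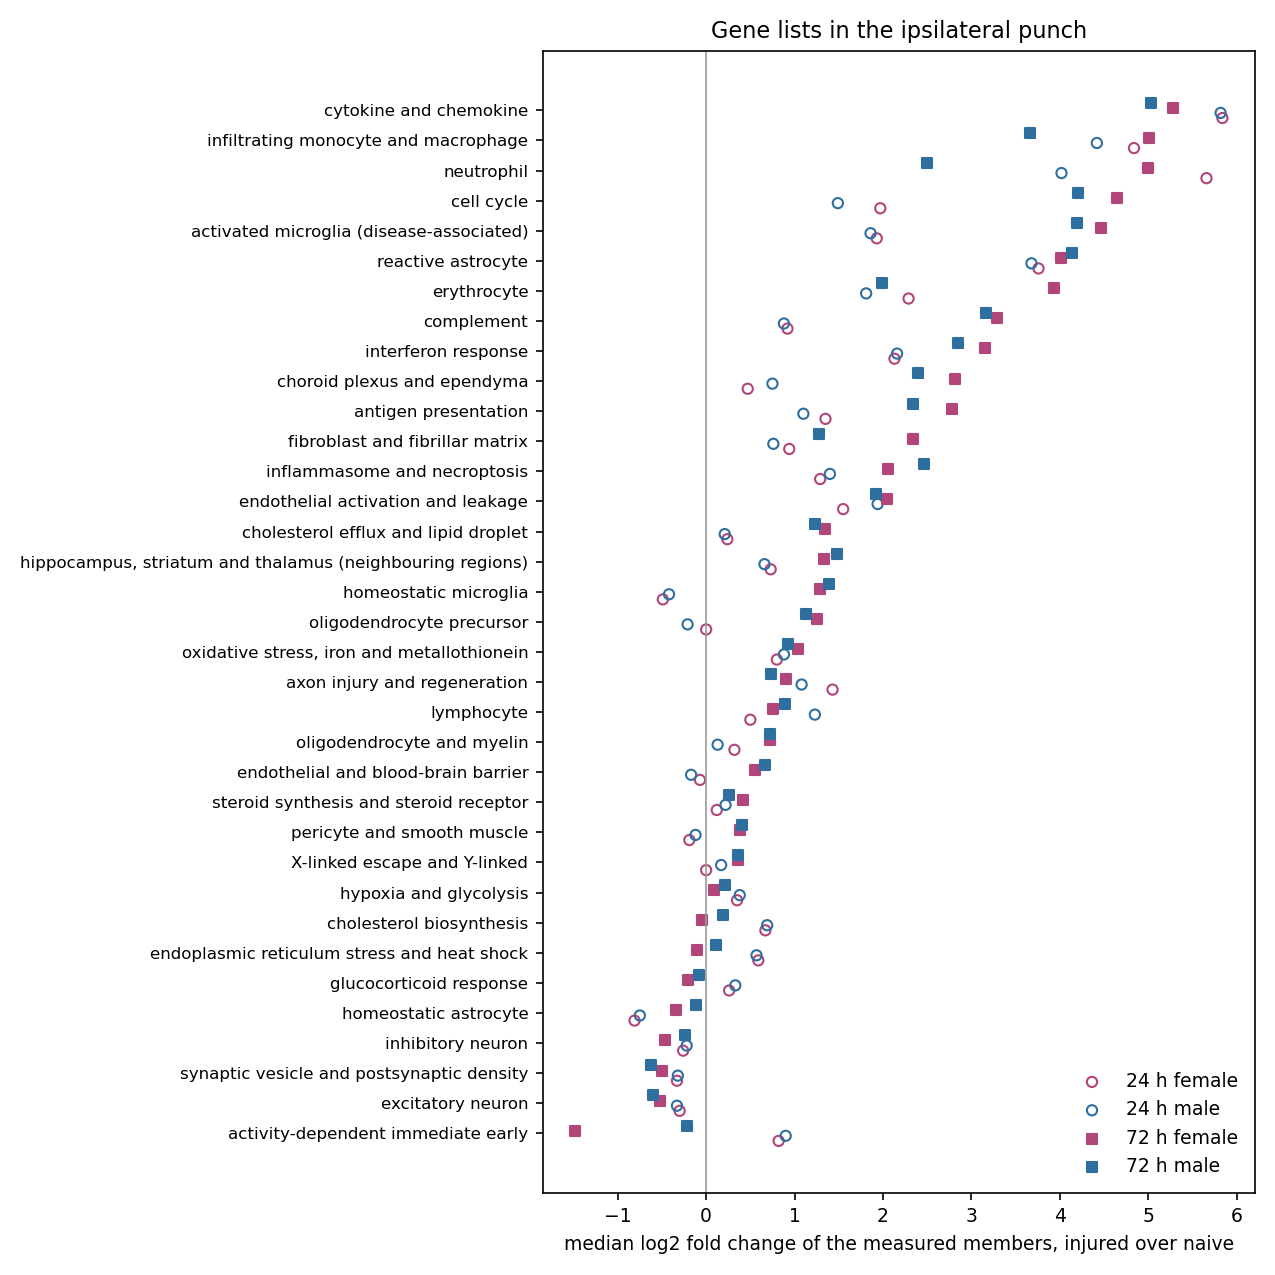
Median log2 fold change of the measured members of each of 35 gene lists, injured over naive ipsilateral cortex, by sex (colour) and time (open circles 24 h, filled squares 72 h). Members without counts in a naive group are plotted at the bound that 3 counts allow, which moves the neutrophil median in females at 24 h from 5.96 to 5.66; the homeostatic microglia median was -0.49 in females at 24 h and 1.29 at 72 h.

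At 72 h the question was the same for the later time. Transcripts of microglia, macrophages and dividing cells were high in the injured cortex of both sexes. Cd5l, a secreted macrophage protein, was at least 1110-fold higher in males, whose naive libraries held no counts of it. Sprr1a was at least 437-fold higher in females and 279-fold higher in males, and the collagenase Mmp13 and the fibroblast gene Lrrc15 at least 221-fold and 234-fold higher in females. Lgals3 (chromosome 14, 47367751 to 47386160) went from 0.228 ± 0.265 to 109 ± 67.6 CPM in the 9 libraries labelled female, with that labelled PF1 among them (log2 fold change 8.70 ± 0.59, adjusted p = 3.42e-15) and reached 9.71 ± 0.71 in 6 males. The transglutaminase Tgm1 rose by 8.67 ± 0.44 in males. Among genes that fell were Etnppl, an astrocyte enzyme of phospholipid breakdown (-2.65 ± 0.44 and -3.11 ± 0.44), Otof (-2.87 ± 0.56 and -2.82 ± 0.56), Tcap (-2.91 ± 0.88 and -3.31 ± 0.93), the prostaglandin synthase Ptgds (-2.83 ± 0.38 in females) and the neuropeptide Cartpt (-2.72 ± 0.44 in males). With 1 library fewer these fold changes (log2) moved by over 1.5 times: in females Lgals3 to 9.41 without CF3; in males Lgals3 to 10.78 without EM3, Etnppl to -3.84 without LM2, Otof to -3.98 without LM2, Tcap to -4.07 without LM2 and Cartpt to -3.37 without LM2.

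All 12 reactive astrocyte genes were again higher, with Gfap at 2700 ± 747 CPM in females and 3370 ± 764 CPM in males (4.88 ± 0.24 and 5.26 ± 0.26; adjusted p = 3.89e-19 and 4.26e-19), and Vim at 4.87 ± 0.25 and 5.05 ± 0.26. Activated microglia genes rose for 13 of 14 in each sex. The lysosomal protein Cd68 was at 4.25 ± 0.27 and 4.01 ± 0.28. Homeostatic microglia genes rose for 11 of 12 in each sex. Olfml3 was at 2.61 ± 0.18 and 2.73 ± 0.19 and P2ry12, which had fallen at 24 h, at 0.61 ± 0.22 and 0.80 ± 0.23 (adjusted p = 0.0211 and 0.00489; without the batch term 0.18 and 0.41, adjusted p = 0.408 and 0.11). P2ry12 also lost its call in females at 0.55 without KF3 (adjusted p = 0.0515) and in males at 0.61 without LM2 (adjusted p = 0.0561). Monocyte and macrophage genes rose for 12 and 11 of 12. Ccr2 was at 5.43 ± 0.56 and 4.36 ± 0.55 and Arg1 at 7.23 ± 0.83 and 6.92 ± 0.91. All 15 cell cycle genes rose in both sexes. Top2a was at 6.19 ± 0.50 and 6.21 ± 0.53 and Ccnb2 at 3.74 ± 0.32 and 4.03 ± 0.34. Cytokine genes rose for 14 and 15 of 16, interferon genes for all 15, complement genes for 12 and 11 of 13 and antigen presentation genes for 11 of 12 in each sex. Cxcl10 was at 7.44 ± 0.59 and 7.00 ± 0.59, Bst2 at 4.11 ± 0.32 and 3.44 ± 0.34, C1qb at 3.29 ± 0.17 and 3.17 ± 0.18 and H2-K1 at 2.09 ± 0.21 and 2.13 ± 0.22. Inflammasome and necroptosis genes rose for 11 of 12 in each sex. Casp8 was at 2.91 ± 0.28 and 2.84 ± 0.29. Neutrophil genes rose for 7 of 9 in females and 4 in males. Csf3r was at 1.78 ± 0.34 and 1.71 ± 0.35, and 0 of 3 lymphocyte genes passed in either sex by edgeR. Adjusted p at 72 h was 6.25e-15 and 2.14e-17 for the reactive astrocyte, 1.74e-13 and 4.08e-15 for the activated microglia, 2.73e-16 and 5.37e-18 for the cell cycle, 1.23e-11 and 2.55e-13 for the cytokine, 4.6e-11 and 1.03e-10 for the complement and 2.89e-09 and 1.05e-09 for the antigen presentation list. It was 2.54e-06 and 9.46e-08 for homeostatic microglia (0.122 and 0.0794 with an estimated correlation), 4.91e-08 and 1.42e-07 for monocytes (0.054 and 0.0613 with an estimated correlation), 1.4e-11 and 6.85e-12 for interferon genes (0.0504 and 0.0452 with an estimated correlation), 3.09e-05 and 5.14e-06 for inflammasome genes (0.122 and 0.0843 with an estimated correlation), 0.00671 and 0.0927 for neutrophils (0.304 and 0.62 with an estimated correlation) and 0.479 and 0.611 for lymphocytes. Adjusted over the list alone, in males 12 rose of the complement genes. Other counts given here stayed. Leaving out 1 library moved these fold changes (log2) by over 1.5 times: in males Ccr2 to 5.18 without EM3, Arg1 to 7.60 without EM2 and Cxcl10 to 7.60 without CM1; in females Arg1 to 8.17 and 6.18 without GF3 or PF2 and Bst2 to 3.50 without LF3.

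More neuronal genes fell at 72 h than at 24 h. Camk2a fell by 1.14 ± 0.14 and 1.04 ± 0.14, Lamp5 (chromosome 2, 136052239 to 136069917) by 2.52 ± 0.35 and 2.63 ± 0.35, and Stx1a by 1.28 ± 0.20 and 1.62 ± 0.21. Excitatory genes fell for 6 and 8 of 12, inhibitory genes for 6 and 5 and synaptic genes for 8 and 9, while 1 excitatory gene rose in females and 1 inhibitory gene in each sex. Without the libraries labelled PF1 ipsi and LF3, which stood apart (a choice made after the data were seen), 9 excitatory, 9 inhibitory and 11 synaptic genes fell in females and none of them rose. Adjusted p was 0.0276 and 0.00317 for excitatory (0.28 and 0.123 with an estimated correlation), 0.0125 and 0.0458 for inhibitory (0.292 and 0.452 with an estimated correlation) and 0.000859 and 5.71e-05 for synaptic genes (0.19 and 0.0965 with an estimated correlation). Immediate early genes fell for 6 of 12 in females, including Npas4 (-3.95 ± 1.30), Nr4a1 (-3.21 ± 0.69) and Egr1 (-2.13 ± 0.47), and for 2 in males, Nr4a1 (-2.11 ± 0.78) and Egr1 (-1.63 ± 0.55), with adjusted p = 0.0243 and 0.283 (0.503 and 0.72 with an estimated correlation). Neither call in males held with 1 library fewer: Nr4a1 was at -1.90, -1.78 and -1.93 without LM2, PM2 or KM3 (adjusted p = 0.0956, 0.106 and 0.0684) and Egr1 at -1.33, -1.22 and -1.44 without LM2, PM2 or KM3 (adjusted p = 0.092, 0.106 and 0.0553). Homeostatic astrocyte genes rose for 3 and fell for 5 of 12 in each sex (list adjusted p = 0.154 and 0.283): the water channel Aqp4 rose by 1.83 ± 0.28 and 2.07 ± 0.30 and the glutamate transporter Slc1a2 had -1.05 ± 0.14 and -1.01 ± 0.15. Oligodendrocyte precursor genes rose for 10 of 12 in each sex (adjusted p = 4.9e-05 and 1.95e-05, and 0.0559 and 0.0452 with an estimated correlation). Gpr17 (chromosome 18, 31942997 to 31949636) was at 1.65 ± 0.18 and 1.30 ± 0.19 and the transcription factor Olig1 at 1.46 ± 0.19 and 1.56 ± 0.20. Myelin genes rose for 5 and 4 of 12, with Cldn11 at 1.60 ± 0.30 and 1.54 ± 0.32 and adjusted p = 0.0409 and 0.0554 (0.547 and 0.625 with an estimated correlation). In females, adjusted over the list alone, 6 fell of the homeostatic astrocyte genes and 6 rose of the myelin genes. So adjusted, in males 2 rose of the inhibitory neuron genes, 0 fell of the immediate early genes, 11 rose of the precursor genes and 5 rose of the myelin genes. All other counts above stayed. Moved by over 1.5 times with 1 library fewer (log2): in females Npas4 to -4.66 and -4.56 without FM3 or PF1.

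Barrier transcripts were higher at 72 h, unlike at 24 h. Cldn5 rose by 1.84 ± 0.18 and 1.58 ± 0.19 (adjusted p = 3.53e-11 and 9.26e-09) and Tjp1 by 0.86 ± 0.12 and 0.70 ± 0.13, the junctional adhesion gene F11r by 1.97 ± 0.19 and 2.03 ± 0.20 and Cdh5 by 1.80 ± 0.20 and 1.42 ± 0.20, whereas Ocln did not pass (0.28 ± 0.19 and 0.41 ± 0.20; adjusted p = 0.253 and 0.11). Ocln passed in males at 0.45 without HM2 (adjusted p = 0.0425). Of 15 endothelial and barrier genes 9 and 10 rose, with adjusted p = 0.000256 and 0.000125 and 0.107 and 0.0843 with an estimated correlation. Endothelial activation genes rose for 11 and 9 of 14 (list adjusted p = 2.31e-06 and 2.45e-06), including Cav1 (2.36 ± 0.19 and 2.07 ± 0.20) and von Willebrand factor Vwf (2.01 ± 0.18 and 2.19 ± 0.19). Fibroblast genes rose for 10 and 5 of 12 and fell for 1 and 1 (list adjusted p = 0.000259 and 0.0145; 0.195 and 0.452 with an estimated correlation). The collagen Col3a1 (chromosome 1, 45311538 to 45349706) was at 4.77 ± 0.62 and 3.09 ± 0.62. Pericyte genes rose for 5 and 5 of 12 and fell for 0 and 1 (list adjusted p = 0.177 and 0.196). Des was at 2.32 ± 0.51 and 2.08 ± 0.52. Red cell genes rose for 5 and 3 of 5 (list adjusted p = 0.00323 and 0.198; 0.212 and 0.625 with an estimated correlation). Hbb-bs was at 4.53 ± 0.69 and 2.17 ± 0.74. Choroid plexus and ependyma genes rose for 3 of 9 in each sex (list adjusted p = 0.0698 and 0.0663). Of the 9 libraries labelled female those of SF1, SF2 and SF3 stood far above the rest for 6 choroid genes, Ttr at 718, 592 and 618 CPM against at most 9.26. Neighbouring-region genes rose for 9 and 8 of 12, with 1 falling in males (adjusted p = 0.0169 and 0.0188, and 0.0968 and 0.0843 with an estimated correlation). The adenosine receptor Adora2a of striatum was at 2.36 ± 0.38 and 2.21 ± 0.42. When members were adjusted over the list alone, in females 10 rose of the barrier genes, 13 rose of the endothelial activation genes, 7 rose of the choroid plexus genes and 10 rose and 1 fell of the neighbouring-region genes. By the same adjustment in males 10 rose of the endothelial activation genes, 6 rose of the pericyte genes and 4 rose of the red cell genes. The remaining counts stayed. With 1 library fewer these fold changes (log2) moved by over 1.5 times: in males Col3a1 to 2.42 and 3.81 without LM2 or EM3; in females Hbb-bs to 3.56 without LF3.

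At 72 h cholesterol synthesis was back near naive levels while genes of lipid handling were high. Of 15 biosynthesis genes 1 rose and 1 fell in females and 3 rose in males (list adjusted p = 0.549 and 0.586). Efflux and lipid droplet genes rose for 8 and 7 of 12 (adjusted p = 2.48e-05 and 2.36e-05, and 0.0771 and 0.0792 with an estimated correlation). The droplet coat protein Plin2 was at 4.41 ± 0.34 and 4.29 ± 0.35 and the exporter Abca1 at 2.45 ± 0.20 and 2.24 ± 0.21. Oxidative stress genes rose for 10 of 12 in each sex (list adjusted p = 2.6e-06 and 2.45e-06). Hmox1 was at 6.87 ± 0.31 and 6.33 ± 0.32 and ferritin Ftl1 at 2.89 ± 0.23 and 2.59 ± 0.25. Hypoxia genes rose for 2 and 5 and fell for 2 of 12 in each sex (list adjusted p = 0.885 and 0.403), and endoplasmic reticulum stress genes rose for 3 and fell for 1 of 12 (list adjusted p = 0.974 and 0.946). Axon injury genes rose for 7 and 6 of 12 and fell for 2 and 1 (list adjusted p = 0.00135 and 0.000325). Atf3 was at 5.39 ± 0.33 and 5.72 ± 0.37. Glucocorticoid response genes rose for 3 and fell for 6 of 12 in females and rose for 3 and fell for 5 in males (list adjusted p = 0.426 and 0.611). The clock gene Per1 was at -1.09 ± 0.23 and -1.30 ± 0.24. Of the steroid genes 4 of 11 rose and 2 fell in each sex (list adjusted p = 0.32 and 0.537): Tspo (chromosome 15, 83563592 to 83574203) reached 5.50 ± 0.47 and 4.47 ± 0.52, Esr1 (chromosome 10, 4611593 to 5005614) 1.55 ± 0.35 and 1.58 ± 0.38 and Pgr -0.58 ± 0.14 and -0.83 ± 0.15, while Esr2 rose in females (2.08 ± 0.56) and did not pass in males (0.92 ± 0.60; adjusted p = 0.237). Esr2 was again near the floor, at 0.726 and 0.43 CPM after injury. The list of X- and Y-linked genes had 4 risers of 9 in each sex (list adjusted p = 0.438 and 0.65). These were the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y, which trace to the ipsilateral library labelled PF1 (female), whose transcripts were male; without it and LF3 Ddx3y went from 10.82 to 2.05 in females (adjusted p = 0.359). Adjusted over the list alone, in females 0 rose and 0 fell of the cholesterol synthesis genes, 12 rose of the oxidative stress genes, 1 fell of the hypoxia genes and 2 rose of the endoplasmic reticulum stress genes. Also in females 5 rose of the steroid genes. Likewise in males 8 rose of the efflux genes, 11 rose of the oxidative stress genes, 2 rose of the endoplasmic reticulum stress genes and 4 rose of the glucocorticoid genes. Other counts given here stayed. Leaving out 1 library moved these fold changes (log2) by over 1.5 times: in females Tspo to 3.73 without LF3 and Esr1 to 0.95 without LF3; in males Tspo to 3.41 without LF3.

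At 72 h 8700 of 19126 genes passed in females (5102 rose, 3598 fell) and 6947 in males (3977 rose, 2970 fell). Batch C held 72 h animals alone, so these changes rest on batch B, in which 4187 and 2997 genes passed with 3 females against 2 and 2 males against 2. These 3 females are PF2, LF3 and the library labelled PF1, and the last 2 stood apart from the others. Without the length trend the share of calls that rose was 44.87% in females and 42.31% in males, against 58.6% and 57.2%, and the median of all genes moved by -0.161 and -0.168. Without the libraries labelled PF1 ipsi and LF3 7748 and 7868 genes passed.

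Setting 72 h directly against 24 h asked what moved between the times. Homeostatic microglia genes rose together, all 12 in each sex. P2ry12 was at 2.72 ± 0.21 and 2.87 ± 0.21. The apelin receptor Aplnr (5.86 ± 0.46 and 4.94 ± 0.46), Cd5l (5.51 ± 0.53 and 5.16 ± 0.56) and the progenitor fatty acid binding protein Fabp7 (4.84 ± 0.39 and 4.64 ± 0.41) rose in both sexes. Chemokine transcripts that attract neutrophils dropped, with Cxcl2 at -7.63 ± 1.22 and -8.28 ± 1.35 and Cxcl3 at -5.57 ± 1.23 and -7.63 ± 1.40, as did the receptor Cxcr2 (-4.18 ± 0.58 and -5.39 ± 0.63), Acod1 (-4.77 ± 0.89 and -4.99 ± 0.99) and Slfn4 (-4.03 ± 0.64 and -4.78 ± 0.69). At 72 h Cxcl2 was at 0 CPM in LF3, PF1, LM2 and PM2 and at 0.166 in PF2, the batch B libraries. In batch C it was at 0 to 1.48 CPM. The size of its fold change therefore rests on values near 0 and is poorly fixed. Barrier genes rose for 12 and 10 of 15. Cldn5 was at 1.91 ± 0.16 and 1.74 ± 0.17, Ocln at 1.01 ± 0.18 and 1.26 ± 0.18 and Tjp1 at 0.68 ± 0.11 and 0.58 ± 0.12. Precursor genes rose for 9 and 8 of 12. Gpr17 was at 2.52 ± 0.18 and 2.49 ± 0.17. Cell cycle genes rose for all 15. Activated microglia genes rose for 12 and 11 of 14 with Trem2, a lipid receptor, at 2.53 ± 0.18 and 2.41 ± 0.19, efflux genes for 11 and 10 of 12, and complement genes for 9 and 7 of 13 with C1qa at 4.38 ± 0.45 and 3.67 ± 0.50. These 7 lists kept adjusted p under the threshold with an estimated correlation, from 0.00929 to 0.0228. Cholesterol synthesis genes fell for 12 and 5 of 15 (adjusted p = 8.64e-08 and 2e-05, and 0.158 and 0.275 with an estimated correlation). Insig1 was at -0.96 ± 0.15 and -0.81 ± 0.16. Immediate early genes fell for 11 of 12 in females and 0 in males (adjusted p = 9.03e-06 and 0.00654; 0.262 and 0.413 with an estimated correlation). Fos was at -3.04 ± 0.60 in females. In all 6320 genes differed in females (3966 rose, 2354 fell) and 4419 in males (2685 rose, 1734 fell). Within batch B, the only batch with both times, 2326 and 1075 differed, of which 80.95% and 86.14% rose. In females, adjusted over the list alone, 1 fell of the barrier genes, 10 rose of the precursor genes, 10 rose of the complement genes and 13 fell of the cholesterol synthesis genes. Further, in females 12 fell of the immediate early genes. So adjusted, in males 12 rose and 1 fell of the barrier genes, 11 rose of the precursor genes, 11 rose of the efflux genes and 8 fell of the cholesterol synthesis genes. All other counts above stayed. Moved by over 1.5 times with 1 library fewer (log2): in males Cd5l to 4.56 without LM2, Fabp7 to 3.98 without LF3, Cxcl2 to -10.77 without PF2, Cxcl3 to -8.27, -8.41 and -6.77 without SM1, PF2 or SF3 and C1qa to 2.34 without LF3; in females Fabp7 to 3.72 without LF3, Cxcl2 to -10.28 and -5.92 without PF2 or RF1, Cxcl3 to -6.52 and -4.28 without PF2 or RF1, Acod1 to -3.55 without RF1, Slfn4 to -3.15 without RF1 and C1qa to 2.27 without LF3.

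The sex comparisons asked which transcripts differed between females and males at each time and whether the response itself differed. Apart from genes of the sex chromosomes almost nothing passed. Xist, the RNA that silences one X chromosome (chromosome X, 103460366 to 103483254), was at 646 ± 246 CPM in naive females and 0.439 ± 0.37 CPM in naive males (log2 difference 10.49 ± 0.81), and the escape gene Eif2s3x (chromosome X, 94188707 to 94212862) was higher in females by 0.60 ± 0.11 in naive cortex and 0.66 ± 0.10 at 24 h. Ddx3y, Eif2s3y, Kdm5d, Uty and the predicted gene Gm29650 completed the 7 genes that differed in naive cortex and the 7 at 24 h. At 72 h 6 differed: Xist (11.53 ± 0.87), the 4 Y-linked genes and Rab10os, a transcript annotated antisense to Rab10 (chromosome 12, 3235504 to 3250377; 0.43 ± 0.08, adjusted p = 0.00436), whose reads cannot be told from those of its partner without a stated strand. Without the batch term Rab10os did not pass (0.43, adjusted p = 0.333). The Y-linked differences at 72 h were reduced by the library labelled PF1 ipsi, Ddx3y being -5.81 with it and -10.80 without it and LF3, and 11 genes passed without them. Of the X- and Y-linked list 2 of 9 were higher in females and 4 lower in naive cortex, 2 and 4 at 24 h, and 1 and 4 at 72 h (4, 5 and 5 higher and 4, 4 and 4 lower adjusted over the list alone; adjusted p = 0.000328, 0.00504 and 0.0159, and 0.00183, 0.029 and 0.146 with an estimated correlation). Within batch A 7 genes differed in naive cortex and 7 at 24 h, and within batch B 0 at each time. Ipsilateral Xist in batch B at 24 h was still at 446.65 to 635.83 CPM in 4 females and 0 to 0.13 in 4 males. The batch B fit thus missed a gene that clearly differs, and its 0 does not speak for an absence of sex differences.

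The change with injury did not differ detectably between the sexes for any single gene. In the ipsilateral punch 0 of 19126 interactions passed at 24 h (299 at unadjusted p under 0.05 by edgeR, 1 after adjustment by DESeq2) and 0 at 72 h (580 unadjusted, 0 by DESeq2), and 0 passed within batch A at 24 h. For Gfap the difference between the sexes in log2 fold change was 0.18 ± 0.26 at 24 h and -0.39 ± 0.26 at 72 h, for Cldn5 0.09 ± 0.20 and 0.26 ± 0.20, for Ocln 0.12 ± 0.21 and -0.13 ± 0.21, for Esr1 0.00 ± 0.43 and -0.02 ± 0.39 and for Pgr 0.10 ± 0.15 and 0.25 ± 0.15. Of the 6733 genes that passed in either sex at 24 h 98.84% had the same sign in the other sex (Pearson r across genes 0.943, genes not being independent replicates), 2499 rose in both sexes where independent lists would share 498.6, 1904 fell in both where independent lists would share 321.6, and 0 went in opposite directions. At 72 h the same-sign share was 99.45% of 9388 genes, 3655 rose and 2604 fell in both, and 0 were opposite. The sexes shared the batch terms of 1 fit, so their estimates are not independent. Leaving out the female LF3, for example, moved Tspo in males at 72 h from 4.47 to 3.41. Part of this agreement may come from the fit, and independent lists are not a fair measure for it. On simulated counts with a sex-dependent 2-fold difference, this design recovered 49.25% at 24 h and 47.76% at 72 h. By the preset list test 5 lists differed at 72 h: erythrocyte (9.58e-08; 4 of 5 genes higher in the female response adjusted over the list alone), fibroblast (4.4e-05) and neutrophil (0.00174) genes had higher log2 fold changes in females, and immediate early (0.00119; medians -1.48 and -0.23 in females and males) and cholesterol synthesis genes (0.00119; medians -0.05 and 0.19) lower ones. With an estimated correlation adjusted p = 0.165 for erythrocyte genes and 0.719 for the other lists, so none held. Of the 24 h interactions no list passed (lowest adjusted p = 0.19).

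**Figure D3:**
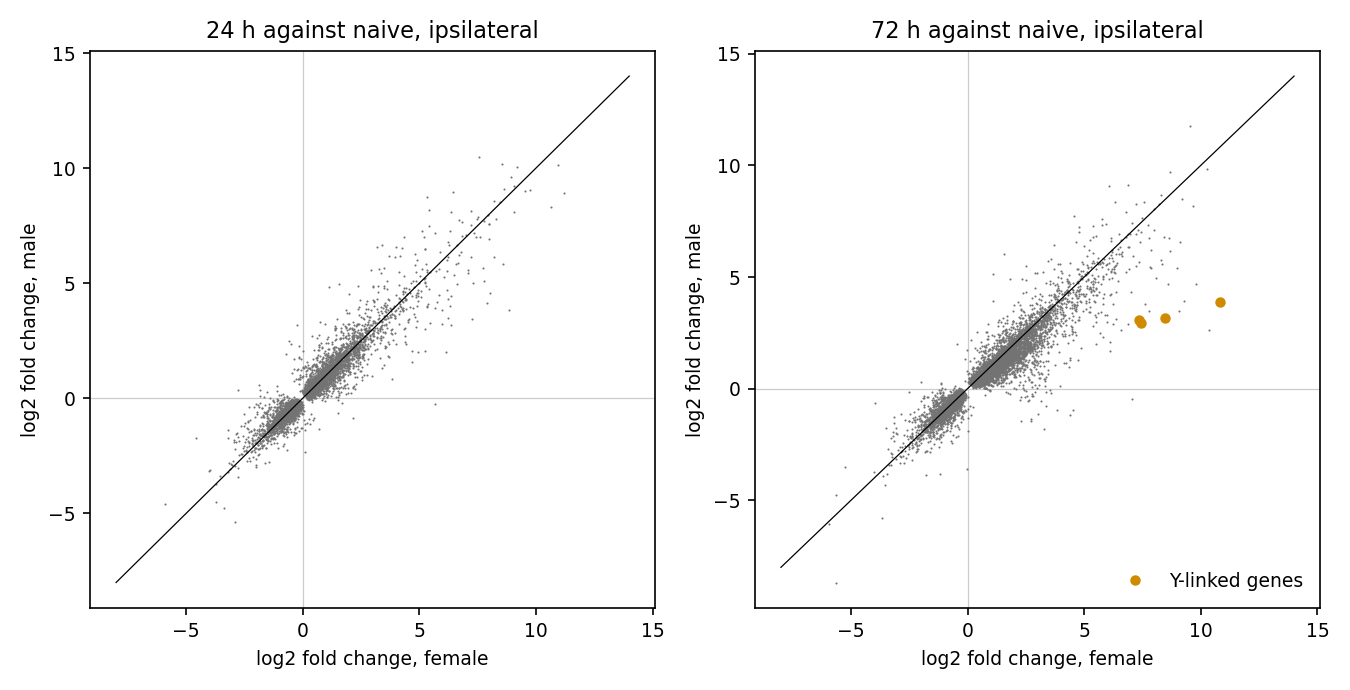
Log2 fold change with injury in females (x axis) against males (y axis), 24 h left and 72 h right, for genes that passed in either sex; the line marks equality. Of the plotted genes 98.84% and 99.45% lie on the same side of 0 in both sexes, and the 4 Y-linked genes off the line at 72 h come from the library labelled PF1 ipsi.

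In the opposite hemisphere the question was whether cortex that was not struck had changed after injury, which against naive mice includes surgery and buprenorphine. At 24 h the lipopolysaccharide binding protein Lbp rose by 1.48 ± 0.27 and 1.67 ± 0.29 in females and males, the metalloproteinase inhibitor Timp1 (chromosome X, 20870166 to 20874735) by 1.60 ± 0.34 and 1.52 ± 0.35 and the proteoglycan Prg4 by 1.31 ± 0.22 and 1.19 ± 0.22, and Lcn2, a siderophore-binding protein of reactive astrocytes, by 3.43 ± 0.67 in females. In males collagens rose (Col3a1 1.11 ± 0.27, Col5a1 1.10 ± 0.20, Col6a2 1.05 ± 0.15), and Car12 (-1.55 ± 0.28), Egr3 (-1.06 ± 0.21) and Nptx2 (-0.95 ± 0.15) fell; Cbln4, a synapse organiser, fell in both sexes (-0.94 ± 0.18 and -1.10 ± 0.18). Gfap did not pass (1.15 ± 0.36 and 0.45 ± 0.34; adjusted p = 0.363 and 0.701). Of 18436 genes 17 passed in females (9 rose, 8 fell) and 185 in males (71 rose, 114 fell), with 0 and 75 in batch A alone and 0 and 0 in batch B. Reactive astrocyte genes rose for 2 of 12 in females (6 adjusted over the list alone; adjusted p = 3.19e-06, and 0.162 with an estimated correlation). In males homeostatic astrocyte genes were lower as a list (0 of 12 fell, 4 adjusted over the list alone; adjusted p = 2.72e-06, and 0.0186 with an estimated correlation), as were inhibitory neuron genes (1 and 3; adjusted p = 0.0171, and 0.0421 with an estimated correlation).

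At 72 h microglial transcripts of the opposite hemisphere were slightly higher. In females 570 genes passed (566 rose, 4 fell), among them Lgals3 (4.61 ± 0.61), Tyrobp (2.44 ± 0.45), C1qa (2.19 ± 0.43), Mki67 (2.27 ± 0.51) and the mitochondrial transcripts mt-Co3 (3.70 ± 0.63) and mt-Co2 (2.75 ± 0.57). This count rested on the contralateral library of LF3: without it and the library labelled PF1 ipsi 9 genes passed, and C1qa (0.38), Tyrobp (0.48), mt-Co3 (0.70) and mt-Co2 (0.34) did not (adjusted p = 0.968 for each). The direction also turned on the batch term: without it 405 genes passed in females, 28.64% of them higher and 77 shared with the 570, and 267 in males, 25.09% of them higher. In males 1 gene passed, Col3a1 (1.94 ± 0.33, adjusted p = 0.0146). The list test was higher for activated microglia (adjusted p = 4.38e-08 and 8.34e-07; 7 and 0 of 13 rose, 9 and 9 adjusted over the list alone), homeostatic microglia (4.92e-06 and 8.34e-07; 3 and 0 of 12, 7 and 4 adjusted over the list alone), complement (0.0024 and 0.00132; 4 and 0 of 12, 4 and 5 adjusted over the list alone), cell cycle (5.24e-07 and 2.2e-06; 1 and 0 of 14, 8 and 1 adjusted over the list alone) and fibroblast genes (9.31e-07 and 2.2e-06; 4 and 1 of 12, 6 and 5 adjusted over the list alone), and these held in both sexes with an estimated correlation (0.0033 to 0.0396). No interaction of sex and injury passed contralaterally at 24 h (584 at unadjusted p under 0.05 by edgeR, 0 by DESeq2) or 72 h (672 unadjusted, 2 by DESeq2). Erythrocyte genes differed as a list at 72 h (adjusted p = 1.04e-13, and 0.0086 with an estimated correlation; 0 of 5 single genes, 5 adjusted over the list alone). Hbb-bs was highest in 3 females, TF1 (66.74 CPM), TF2 (93.26) and TF3 (67.76), while SF1, SF2, SF3 and PF1 (7.35 to 17.67) lay within the range of males (5.03 to 23.07). Within batch B 0 genes passed in either sex at 72 h.

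Within animals, the injured side was set against the other side with the animal as a block, taken from the animal named in the labels. Between the sides of naive animals 0 genes passed in females (475 at unadjusted p under 0.05 by edgeR, 0 by DESeq2) and 0 in males (680 unadjusted, 0 by DESeq2). Without the low-count filter 9 and 44 passed, and without the libraries labelled PF1 ipsi and LF3 1 in males. At 24 h Sprr1a, without contralateral counts in 8 males, was at least 177-fold higher on their injured side; Tgm1 was higher by 6.93 ± 0.29 and 7.86 ± 0.30, Clec4d by 6.33 ± 0.37 and 7.30 ± 0.35 and the pentraxin Ptx3 by 6.01 ± 0.35 and 6.42 ± 0.34, and Fmod (-3.86 ± 0.38 and -3.81 ± 0.35), Myoc (-3.56 ± 0.37 and -3.85 ± 0.35) and Slc22a8 (-3.17 ± 0.24 and -3.21 ± 0.23) were lower. At 72 h Clec4d, without contralateral counts in 6 males, was at least 218-fold higher on their injured side, Arg1 (8.10 ± 0.32 and 7.68 ± 0.40) and the glycine transporter Slc6a5 (7.85 ± 0.55 and 7.42 ± 0.67) were higher and Ptgds (-2.89 ± 0.23 and -2.67 ± 0.28) and Lamp5 (-2.37 ± 0.16 and -2.35 ± 0.19) lower. At 72 h 11 and 10 of 12 excitatory, 10 and 9 inhibitory and 11 and 11 synaptic genes were lower in females and males (adjusted p with an estimated correlation 0.0175 and 0.0181, 0.0246 and 0.0492 and 0.0246 and 0.0262). Cholesterol synthesis genes were higher at 24 h for 15 of 15 in each sex (adjusted p = 6.66e-11 and 2.86e-10). The numbers of genes with a side difference were 6417 (3373 higher, 3044 lower) and 7242 (3722, 3520) at 24 h and 10876 (5437, 5439) and 9250 (5039, 4211) at 72 h, of 19946 tested; without the animal block they were 5231, 6010, 10042 and 8032. The side difference itself differed by sex for 0 genes at 24 h (529 unadjusted by edgeR, 0 by DESeq2) and for 5 at 72 h: Ddx3y, Kdm5d, Eif2s3y, Uty and Gm29650, all from the library labelled PF1 ipsi. Without it and LF3 none of these 5 passed and 1 other gene did, Tph1, which was named after its value was seen.

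Plasma steroids, given as log10 values, separated the sexes by testosterone. It averaged -2.19 ± 0.42 in 7 naive females and -0.83 ± 0.27 in 6 naive males (log10 of ng/ml; difference -1.36, exact permutation p = 0.00117, adjusted p = 0.0175 over 30 tests, two-sided), and -2.29 ± 0.28 in 23 females and -0.75 ± 0.52 in 21 males over all times (permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 0.0003). In 17 of 44 animals, all female, testosterone stood at the same lowest value. Androstenedione, a precursor of testosterone, was -1.70 ± 0.26 in naive females, -2.11 ± 0.32 at 24 h and -2.24 ± 0.34 at 72 h; the 72 h difference of -0.54 did not pass (exact permutation p = 0.00647, adjusted p = 0.0647), nor did the 24 h difference (-0.41, p = 0.0256 by exact permutation, adjusted p = 0.192). Dehydroepiandrosterone was 0.42 higher in males at 72 h (0.99 ± 0.48) than in naive males (0.57 ± 0.20), without passing (exact permutation p = 0.0723, adjusted p = 0.325). Batch C holds 72 h animals alone, so within batch each 72 h difference rests on batch B, with 10 arrangements, too few to pass by exact permutation. There androstenedione in females differed by -0.03 (exact permutation p = 1), dehydroepiandrosterone in males by 0.06 (exact permutation p = 0.9) and estradiol in males by 0.22 (exact permutation p = 0.9), the last in the opposite direction to the value that follows. Estradiol, labelled in pg/ml with a scale that could not be settled from the labels, was -2.73 ± 0.30 in naive males and -3.05 ± 0.36 at 72 h (exact permutation p = 0.113, adjusted p = 0.424), and progesterone passed in no test. Of the 30 tests 2 passed. Within sex and time no ipsilateral transcript followed any of the 5 hormones after adjustment by edgeR: 0 genes each for testosterone (males, 577 at unadjusted p under 0.05), androstenedione (569), dehydroepiandrosterone (1390), progesterone (1845) and estradiol (510). Only progesterone slopes were simulated (2-fold per 10 times the level, 89.55% recovered).

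**Figure D4:**
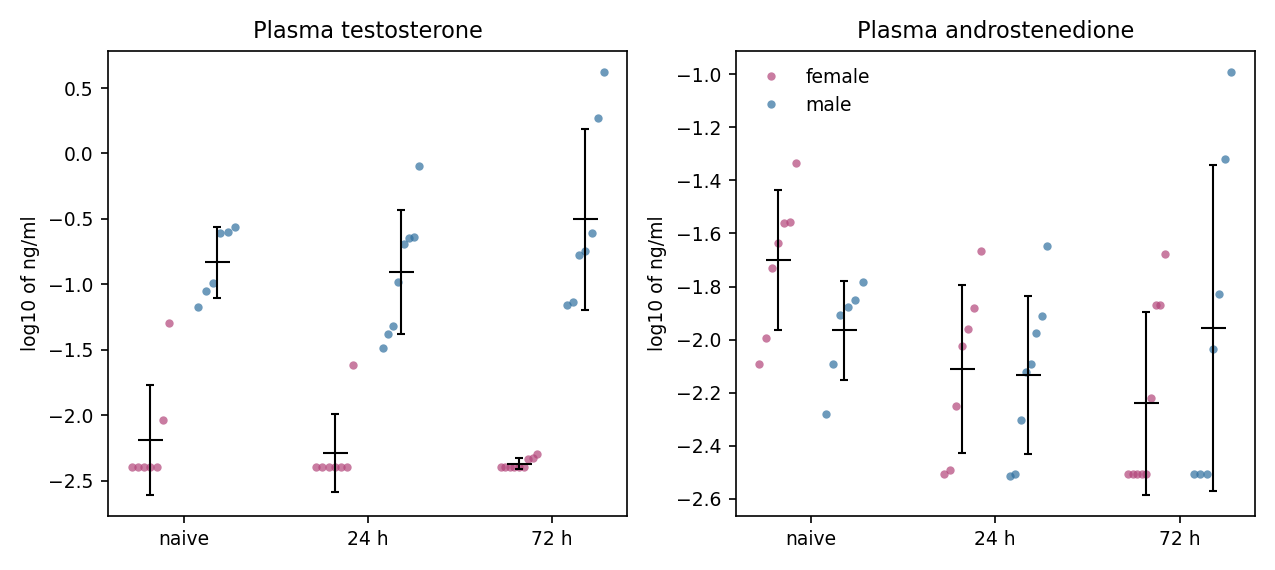
Plasma testosterone (left) and androstenedione (right) per animal, in log10 of ng/ml, by sex and time, with mean and SD. Female testosterone sits at the lowest value, -2.40, in 17 animals.

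The labels' sex was checked against Xist and the summed CPM of Ddx3y, Uty, Kdm5d and Eif2s3y. Of 46 female-labelled libraries 45 and of 41 male-labelled libraries 41 had the transcripts of their label. The exception was the library labelled PF1 ipsilateral, with Xist at 0.11 CPM and a Y-linked sum of 147.96 CPM, where the other 45 female libraries ranged from 114.14 to 1107.26 and from 0 to 0.42 CPM. The unassigned ipsilateral library of PM1 had Xist at 489.39 CPM and a Y-linked sum of 0.

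**Figure D5:**
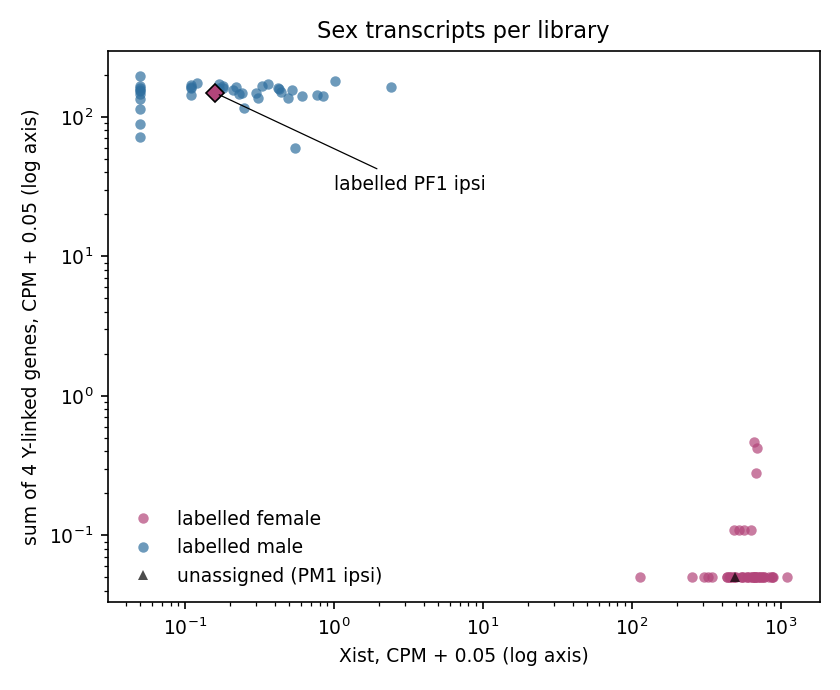
Xist (x axis) against the sum of 4 Y-linked genes (y axis) per library, both in CPM with 0.05 added and on log axes, coloured by labelled sex. The library labelled PF1 ipsilateral (diamond) lies among the males at 0.11 and 147.96 CPM, and the unassigned PM1 ipsilateral library (triangle) among the females at 489.39 and 0 CPM.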

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

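The tests of explanations below were chosen after the pattern was seen. Of 162 group tests (nominal 5%) 34 had a library or animal far from its group. The chance rate was not tested.

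The library labelled PF1 ipsilateral carries male transcripts, and it produces the only genes whose side difference differs by sex at 72 h: Ddx3y (9.52), Kdm5d (8.45), Eif2s3y (7.59), Uty (7.41) and Gm29650 (4.86). An exchange with the unassigned PM1 ipsilateral library predicts female transcripts there, and that library has Xist at 489.39 CPM. A mixture of female and male tissue predicts appreciable Xist in the library labelled PF1 ipsi, which has 0.11 CPM. An exchange of the 2 libraries may therefore explain both, in line with 489.39 and 0.11 CPM, although an error in the labels of tissue or of libraries cannot be told apart here.

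Both libraries of LF3 stand apart in females at 72 h: the ipsilateral total is lowest (10.6 M), mitochondrial genes hold 7.8% contralaterally and 10.48% ipsilaterally, Slc17a7 reaches 5953.42 and 7517.64 CPM, Cldn5 314 and 221 CPM, Tjp1 falls to 62.2 CPM contralaterally, Pgr reaches 121 CPM contralaterally and Esr1 14.6 CPM ipsilaterally. Slc17a7 is scaled to total counts, the other genes to TMM-scaled libraries (Slc17a7 there 9440 and 9700 CPM). LF3 contra deviates with gene length (Spearman rho = -0.375 over genes, no p). So do KM2 and LM2 contra (batch B, per-library rho -0.508 and -0.485, LF3 -0.519). A shift toward short genes in library making as the whole cause predicts that these gene values no longer stand apart once the trend with gene length is removed from each library. Of 7 flagged gene values 6 still did, all but Cldn5 ipsilaterally, and Slc17a7 in LF3 then stood at 11500 CPM contralaterally (9440 before, both on TMM-scaled libraries) against at most 1540 in the others. That argues against this shift as the whole cause. More excitatory neurons in the punch cannot be told from this: the median deviation of that list is 0.86, with 8 members above and 3 below every other library. What set LF3 apart stays open.

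Ttr is at 718, 592 and 618 CPM in the ipsilateral libraries of SF1, SF2 and SF3, against at most 9.26 CPM in the other 6 females at 72 h. Choroid plexus tissue in the punch predicts other choroid genes there, and 5 other members (Folr1, Kl, Clic6, Kcne2 and Otx2) are higher in all 3 than in every other library of the group. Carry-over between libraries predicts Ttr elsewhere in batch C, and 0 of 17 other libraries exceed 50 CPM. Tissue at the edge of the punch may explain these values, given 5 members and 0 libraries.

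Further values far from their group were total counts of DF2 ipsi (26.36 M), SF3 contra (21.71), GF3 ipsi (19.52) and TM1 ipsi (24.73). Mitochondrial shares were low in KF3 ipsi (2.35%) and LM2 contra (2.8%). Ttr was high in DF2 contra (5.77 CPM), KF2 contra (20.24), GF2 ipsi (34.56), DM2 contra (5.99) and CM1 ipsi (3.36), and Slc17a7 in KF3 contra (1682.88). Contralateral Gfap was high in QF1 (821 CPM), TF2 (491), RM1 (267) and PM2 (495). Tjp1 was low in LM2 contra (71.5 CPM), Esr1 high in QF1 ipsi (7.39), and Pgr high in RF2 ipsi (47.3) and low in LM2 contra (38.2). Among hormone levels testosterone was high in QF2 (-1.61) and CF2 (-1.29), dehydroepiandrosterone low in TF2 (-0.90) and estradiol high in PM1 (-2.25).

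The ipsilateral response differed between times for 6320 genes in females and 4419 in males. The unassigned PM1 ipsilateral library had Gfap at 2580 CPM (highest of 13 naive ipsilateral libraries 115), Lgals3 at 91.9 (0.759) and Tyrobp at 65.0 (9.94).

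Other splits of the same libraries, 31 with the real one, test whether as many calls arise by chance. The real split called the most genes, 1 of 31, in the comparisons that follow. Ipsilaterally these were females and males at 24 h (5572 genes against 3126 in the highest other split, and 5564 against 57) and at 72 h (8700 against 1930 and 6947 against 2769). So it was for 72 h against 24 h (6320 against 484 and 4419 against 368). Contralaterally they were females at 24 h (17 against 1), males at 24 h (185 against 56) and females at 72 h (570 against 5, although 9 were left without the libraries labelled PF1 ipsi and LF3). The sides, fitted on each group's animals alone, gave 6359 against 0 and 8904 against 4 at 24 h, and 8741 against 6962 and 9355 against 1 at 72 h. A share of 1 of 31 is the smallest these splits can give, and it was not adjusted over the comparisons. Outside the sides, labels were exchanged across batches, so the other splits lack the tie of 72 h to batch C, and a batch shift was not tested. The splits with 398 and 2425 calls by sex, many times the real 7 and 6, point to a structure of the samples that was not traced. Chance cannot be excluded for the number of calls by sex (naive 7 against 398, 3 of 31; 24 h 7 against 11, 3 of 31; 72 h 6 against 2425, 12 of 31), for contralateral males at 72 h (1 against 1, 2 of 31) or for sex by side at 72 h (3 against 3, 3 of 31, fitted on the 72 h animals alone, where 3 genes passed instead of the 5 of all animals). Where 0 genes passed all 31 of 31 splits are as large by definition, so this test says nothing there: sex by injury ipsilaterally (highest other 1 at 24 h and 88 at 72 h) and contralaterally (5 and 1), naive sides (1 in females and 0 in males) and sex by side at 24 h (0).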

How the results depend on the processing

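The alternatives without the libraries labelled PF1 ipsi and LF3 and without the length trend were chosen after the results were seen; the others were planned. Of 2504 values of named genes under other settings 2395 kept direction and side of the threshold, 103 lost the call, 6 gained it and 0 reversed; with 1 library left out 12616 of 12642 kept them. The cause was not tested unless stated.

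Within batch B, with fewer animals, 1693 and 1445 genes passed in females and males at 24 h, 4187 and 2997 at 72 h, 2326 and 1075 for 72 h against 24 h, and 0 for sex at each time and for each contralateral comparison. Within batch A contralateral counts at 24 h were 0 and 75. DESeq2 called 3 genes by sex in naive cortex, 1 for sex by injury at 24 h ipsilaterally and 2 at 72 h contralaterally, 60 and 363 contralaterally at 24 h, 86 and 12 at 72 h, and 2 for sex by side at 72 h. Without the batch term 1 gene passed by sex at 72 h, 267 in contralateral males at 72 h and 2 for progesterone. With the animal-code letter as block 11 genes passed by sex at 72 h. Without the low-count filter 82 passed in contralateral males at 24 h, 9 and 44 for the naive sides, and 47 and 44 for sex by side at 24 and 72 h. Without the animal block, the pairing of sides, 0 passed for sex by side at 72 h, and no other side count moved by over 1.5 times. Ranks of the level gave 3 genes for androstenedione, and leaving out 2 animals gave 2 for it and 1 for progesterone. The estimated correlation left 69 of the 202 list calls outside the comparisons of sides.

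Without the libraries labelled PF1 ipsi and LF3 11 genes passed by sex at 72 h, 74 and 742 contralaterally at 24 h, 9 and 9 at 72 h, 1 for naive male sides and 1 for sex by side at 72 h. Without the length trend 110 and 7 passed contralaterally at 72 h and 1 for their interaction.

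With each ipsilateral library left out, counts ranged from 5030 to 7160 and 4984 to 7107 at 24 h in females and males, 8086 to 8966 and 6159 to 7864 at 72 h, 4891 to 7070 and 3158 to 5165 for 72 h against 24 h, 7 to 8, 7 to 9 and 6 to 8 by sex in naive, 24 h and 72 h cortex, and 0 to 0 for the interactions. RLE size factors moved no count by over 1.5 times, and both hormone calls kept their side under ranks and under permutation within batch. Small effects can be missed: at 1.5-fold 17.91% of simulated sex by injury differences were recovered at 24 h.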

Other observations

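The tests named here were chosen after the results were seen.

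Library composition moved with gene groups. In LF3 contra the immediate early genes stood 2.07 log2 units above the other females at 72 h (11 of 12 above every other library), erythrocyte genes 1.84, neutrophil genes 1.26, activated microglia genes 0.90 (7 of 13 above and 6 below every other library) and antigen presentation genes 0.82, while monocyte genes stood at -0.96 and inflammasome genes at -0.83. With LF3 left out along with the library labelled PF1 ipsi, the 72 h contralateral median of excitatory genes in females went from 0.41 to -0.09 and that of immediate early genes from 0.04 to -0.60. The contralateral list results for microglia kept their direction, the homeostatic microglia list included.

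Some list medians moved when batch B was fitted alone, which also leaves fewer animals, so the cause was not separated. There the choroid plexus median in females at 24 h went from 0.47 to -0.54, and that of neutrophil genes in males between 72 and 24 h from -2.11 to 0.23. Erythrocyte genes had higher log2 fold changes in females than in males at 72 h contralaterally (adjusted p = 1.04e-13 over lists by camera), and this held without the libraries labelled PF1 ipsi and LF3 (3.09e-11). Hbb-bs was highest in TF1, TF2 and TF3, while SF1, SF2, SF3 and PF1 lay within the range of males. The difference was thus not shared by all females.

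Repeated hormone values were common: 17 of 44 animals shared 1 testosterone value (-2.40, the lowest), 10 shared 1 androstenedione value (-2.51) and 11 shared 1 estradiol value (-3.20, the lowest).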
